A study of Arabidopsis thaliana with 6 samples.

How the data were processed

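The series holds anti-FLAG ChIP-seq of Arabidopsis seedlings fixed with 1% formaldehyde for 10 minutes and sonicated, sequenced as paired ends on an Illumina instrument: 2 ChIP libraries of tagged CND1-FLAG plants, 2 ChIP libraries of untagged Col-0 plants and 1 input of each genotype. Per the submitters' processing notes, reads were trimmed with fastp 0.19.11, aligned with BWA 0.7.12 to TAIR10, and peaks were called with MACS2 2.1.0. The authors gave 1 list of annotated peak summits per ChIP library. The input used for each list and the significance threshold are not given in the sources used here, and the smallest −log10 q in each list was 1.30. Per the file headers, the deposited signal value is a ratio, the fold enrichment of the summit over its local background. The deposited p and q columns are on the −log10 scale, and the deposited score is an integer score equal to 10 times −log10 q, rounded down. The other deposited columns, positions, widths and distances to gene starts, are in base pairs, counted from 1 on TAIR10. Each summit carries the gene and the feature that the authors' annotation assigned, where promoter means within 3 kb on either side of a gene start.

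Samples were grouped by genotype from the labels. The regions, tests, gene lists, pericentromere windows, named-gene rule and alternatives were chosen before the data were examined. Lines of a list with the same start and end were joined to 1 peak, whose fold and assigned gene are those of the summit with the highest fold and whose −log10 q is the highest of its summits. Peaks of the 4 lists that shared at least 1 bp were merged to regions, which took the highest fold and −log10 q of each list, the feature of the strongest tagged peak and, for the gene lists, the genes of all their tagged peaks. A region was tagged-specific when both tagged lists and no Col-0 list had a peak in it, and shared when both tagged lists and at least 1 Col-0 list had one. Peak numbers were compared by an exact two-sided permutation test of the difference of means, for which 2 against 2 libraries give no p below 0.333. Overlap between lists was set against 1000 random placements of the peaks within their chromosome, one-sided, with a smallest p of 0.000999. Medians of fold and −log10 q were compared within each tagged list by two-sided permutation tests with 100000 resamples. Shares of features, chromosomes and pericentromeres and the gene lists were compared by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over 5 features, 7 chromosomes (both organelle genomes among them) or 7 lists and a threshold of 0.05. Lists were tested against the other annotated nuclear genes of the reference gene table of TAIR10.1, 37899 genes in all, and all 12573 genes that the lists assign were found in it by identifier. These tests count regions and genes, which are not biological replicates.

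Genes were named by this rule: the 25 tagged-specific regions with the best rank, the rank being the worse of the ranks by fold in the 2 tagged lists, up to 4 members of each gene list by the same rank, organelle regions of both tagged lists with a summary, the 5 regions of all 4 lists with the best worst rank, and the CND1 locus where named. The sources used here do not name the CND1 locus, so no value is given for it. ATR, LIG4, ERCC1, ORA47, LHCB1.3, FNR1, UBQ10 and the genes named in the closing section fall outside the rule and were chosen after their values were seen.

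Depth was worked out from the summits, since MACS2 computes fold as pile-up plus 1 over background plus 1 and takes p from a Poisson distribution. Solving both for each summit gave whole pile-ups for 99.99% of the summits of each tagged list, and 1 scale factor for each Col-0 list, 0.723 and 0.739, found on 25 and 21 summits, gave whole pile-ups for all summits held out. The input was scaled by 0.855 and 0.767 for CND1-FLAG replicates 1 and 2. Fragments per kb follow from the lowest background in each list and its smallest peak width, taken as the fragment length. These depths carry no counting interval, since library totals were not used. The limit of 1 fragment per position and strand was taken as 2 times that width, 652 and 662 fragments for CND1-FLAG replicates 1 and 2. It is approximate, since a mitochondrial summit of replicate 1 lay at 100.9% of it. On simulated lists 368 of 368 tagged-specific and 1093 of 1093 shared regions were found, the gene list test called 0.329% of lists with an odds ratio of 1, 17.6% with 2 and 83.1% with 4, and 99.8% of unscaled and 99.7% of scaled pile-ups were recovered. The simulated regions lay too far apart for neighbours to merge, so that check covers the sorting into classes alone. All 7 lists had the same odds ratio at once, which makes the adjusted test easier to pass than when 1 list differs.

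Alternatives were −log10 q of at least 5, fold of at least 2, the top 50% of each list, lists of equal length, reciprocal overlap of 50%, an untagged peak within 500 bp counted as shared, each library left out in turn, a replicate block, covered length in place of counts, other gene backgrounds, and 10000 random lists matched on gene length in 20 bins. Where an alternative dropped peaks, a region that lost all its Col-0 peaks but kept both tagged ones counted as tagged-specific. Sequence motifs were not tested, since no genome sequence was used here, and the inputs' own data were not analysed here. The work used Python 3.11.15 with NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.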

Results

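Chromatin of Arabidopsis thaliana seedlings was immunoprecipitated with an anti-FLAG antibody in 2 genotypes: plants that carry FLAG-tagged CND1, pCND1-Flag in the cnd1-3 background, and untagged Col-0 plants. The Col-0 libraries hold no FLAG tag, so the peaks called in them give the background of antibody and chromatin. Each genotype has 2 ChIP libraries and 1 input library, 6 samples in all, and the peak lists of the 4 ChIP libraries were analysed. The labels do not say whether the 2 libraries of a genotype came from separately grown plants. Read totals are not given in the sources used here. The fold enrichment and p-value of each summit allowed the number of fragments behind the lists to be worked out, which came to 84.6 and 76.0 ChIP fragments per kb for CND1-FLAG replicates 1 and 2, and to 158 and 155 for Col-0 replicates 1 and 2. The tagged mean was 80.3 ± 6.12 fragments per kb and the Col-0 mean 157 ± 2.44 (SD, n = 2 each), so the tagged libraries were the shallower ones, at 0.513 of the Col-0 depth. The peaks of both tagged lists were called over 1 input of 99.01 fragments per kb, and those of both Col-0 lists over 1 input of 114 fragments per kb.

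The first comparison asks how much more chromatin was recovered as peaks when the tag was present. The CND1-FLAG lists held 13044 and 10538 peaks and the Col-0 lists 6152 and 5722. The mean was 11791 ± 1772 in tagged plants and 5937 ± 304.1 in Col-0 (SD, n = 2 each), a ratio of 1.99, and both tagged lists were longer than both Col-0 lists. Peaks covered 7392 and 6028 kb in the tagged lists against 3487 and 3270 kb in the Col-0 lists, with median widths of 459, 464, 473 and 475 bp in the same order. The exact two-sided permutation test gave p = 0.333 with n = 2 per group, the smallest value that 2 against 2 libraries can give. The ratio was larger among stronger peaks: it was 3.48 for peaks with −log10 q of at least 5 and 6.43 for peaks with a fold enrichment of at least 2, which left 5368 and 4112 tagged peaks and 753 and 722 Col-0 peaks. These thresholds were the same for lists that rest on different depths, inputs and scaling. The median fold was 1.92 and 1.905 in the tagged lists and 1.66 in each Col-0 list, so the larger ratios cannot be told apart from a shift of the whole scale.

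The second comparison asks whether tagged and untagged chromatin gave peaks at the same places. Of the Col-0 peaks as listed, 74.8% of those of replicate 1 and 75.5% of those of replicate 2 overlapped a peak of at least 1 tagged list. In the other direction 40.6% and 43.9% of the peaks of CND1-FLAG replicates 1 and 2 overlapped a Col-0 peak, and 59.4% and 56.1% did not. Between the tagged lists, 63.8% of the replicate 1 peaks overlapped a replicate 2 peak and 78.8% the other way round. Between the Col-0 lists these shares were 60.0% and 64.6%. The tagged lists are longer, and with lists of equal length the shares between genotypes were 35.8% to 38.3%, against 61.0% to 61.9% within a genotype. With −log10 q of at least 5, 16.5% and 16.7% of the peaks of CND1-FLAG replicate 1 and 20.3% and 20.6% of those of replicate 2 overlapped a peak of a Col-0 list, compared with 30.4% and 32.4%, and 33.3% and 35.7%, as listed. At that threshold the Col-0 lists shrank to 1936 and 1887 peaks and the tagged lists to 7803 and 5497, and 58.6% to 68.0% of the Col-0 peaks still overlapped a peak of a given tagged list, compared with 61.3% to 69.4% as listed. Each of the 6 pairs of lists shared more peaks than any of 1000 random placements of the peaks within their chromosomes, one-sided permutation p = 0.000999, the smallest value that the placements can give. Peaks are not biological replicates, and these p-values speak of positions along the genome.

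**Figure D1:**
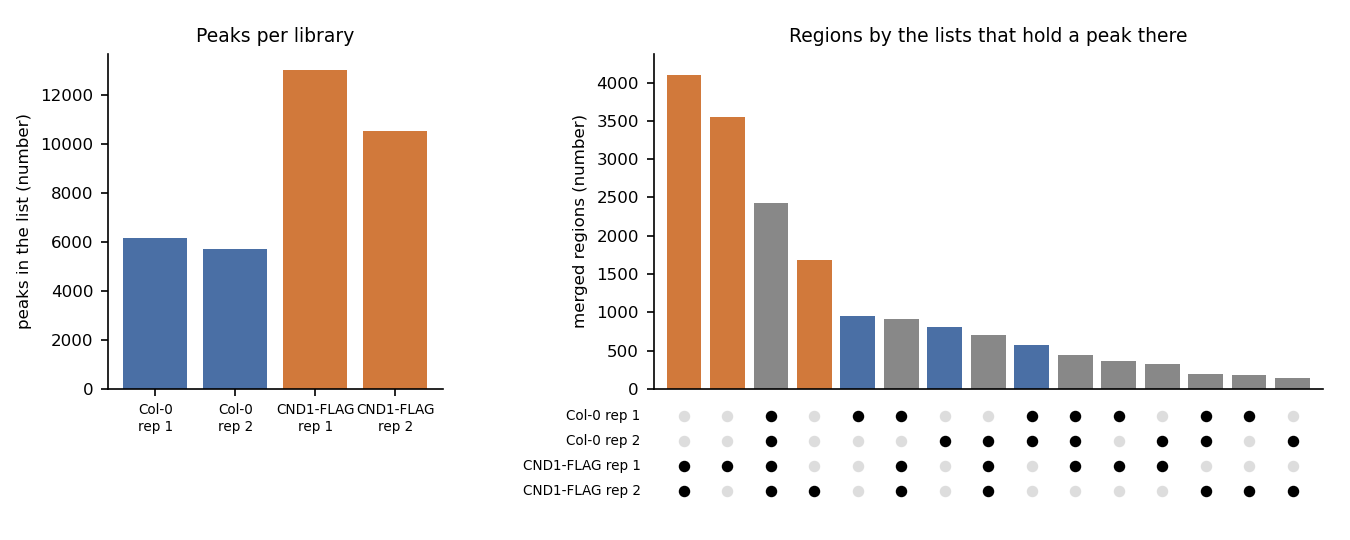
Number of peaks per library (left), and number of merged regions by the set of lists that hold a peak there, marked by black dots (right), in orange for tagged lists alone, blue for Col-0 lists alone and grey for both. The CND1-FLAG libraries had 13044 and 10538 peaks against 6152 and 5722 in Col-0, and the largest set, 4102 regions, was called in both tagged lists and in neither Col-0 list.

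The third comparison takes the regions called in both CND1-FLAG lists and in neither Col-0 list, here called tagged-specific. The genotypes differ in the cnd1-3 background and the transgene as well as in the tag. The class rests on whether a peak was called. Col-0 signal at these regions was not measured, so some can hold Col-0 signal below the calling threshold. Median fold was lower in the Col-0 lists, and a shift of the whole scale can move weak shared sites into the class. Merging the 4 lists gave 17347 regions, of which 4102 were tagged-specific, while 573 were found in both Col-0 lists alone. Longer lists by themselves give the tagged pair more such regions. The count for the Col-0 pair was not worked out with lists of equal length. Regions found in just 1 tagged and 1 Col-0 list numbered between 146 and 365 per pair of libraries. Another 4038 regions were called in both tagged lists and in at least 1 Col-0 list, 2426 of them in all 4 lists, and these are called shared. The tagged-specific regions of the nuclear genome numbered 4011 and were assigned to 3690 genes, with a median width of 520 bp against 717 bp for shared regions. Shared regions join peaks of more lists, which by itself can widen them. The count depends on how peaks are chosen: it was 2719 with −log10 q of at least 5, 2115 in the top 50% of each list and 1618 with lists of equal length. Without CND1-FLAG replicate 2 it was 7753, since 1 tagged list then suffices.

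The strongest tagged-specific regions lay at or near the starts of genes of several kinds. The first by rank was at AT1G74929 (chromosome 1, 28143942 to 28145010, TAIR10), with a fold enrichment of 7.88 and 8.01 in CND1-FLAG replicates 1 and 2. In the TAIR10.1 gene table this region also overlaps ORA47 (AT1G74930), a transcription factor of the AP2/ERF family. The second was at DBP (AT2G45820; chromosome 2, 18864178 to 18864759), which encodes a remorin, a protein of plasma membrane domains, with 5.26 and 4.75. The region at CYP707A3 (AT5G45340; chromosome 5, 18368858 to 18370146), an 8'-hydroxylase that breaks down abscisic acid, had 4.83 and 5.16. The region at U5.1b (AT3G08605; chromosome 3, 20736602 to 20737094), a gene for the spliceosomal U5 snRNA, had 5.08 and 4.16. AT1G30640, annotated by similarity as a serine/threonine protein kinase, had 2 of the regions, with 4.30 and 4.24 at 10864411 to 10864929 and 3.95 and 3.41 at 10862643 to 10863826 on chromosome 1. CERK1 (AT3G21630), the receptor kinase for chitin, had 3.43 and 3.93 at 7616127 to 7617543 on chromosome 3. SYP121 (AT3G11820), a syntaxin of the plasma membrane, had 3.48 and 3.21 at 3729443 to 3730044 on the same chromosome. CPK3 (AT4G23650), a calcium-dependent protein kinase, had 3.48 and 3.56 at 12326883 to 12327565 on chromosome 4.

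The other named regions lay at LLG1 (AT5G56170), a GPI-anchored protein, with 4.09 and 3.48, and at MEE14 (AT2G15890), with 3.998 and 3.72. GASA7 (AT2G14900), of the gibberellin-regulated GASA family, had 3.71 and 3.58, and AGP20 (AT3G61640), an arabinogalactan protein, had 3.57 and 3.24. AT4G16940, whose product is most similar to the immune receptor SNC1, had 3.69 and 4.20. AT3G27550, with a CRM domain by similarity, had 3.97 and 3.73, and AT3G27200, similar to uclacyanin, had 3.69 and 3.89. The remaining loci were AT2G41650, AT3G56085, AT3G23170, AT2G03230, AT1G68680, AT3G19030, AT4G27657, AT4G25170 and AT2G27260. Across all 25 regions, at 24 genes, the fold enrichment ran from 3.39 to 7.88 in replicate 1 and from 3.15 to 8.01 in replicate 2. By the strongest tagged peak of each of the 25 regions, 21 lay within 1 kb of the start of the assigned gene and 10 overlapped that start.

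**Figure D2:**
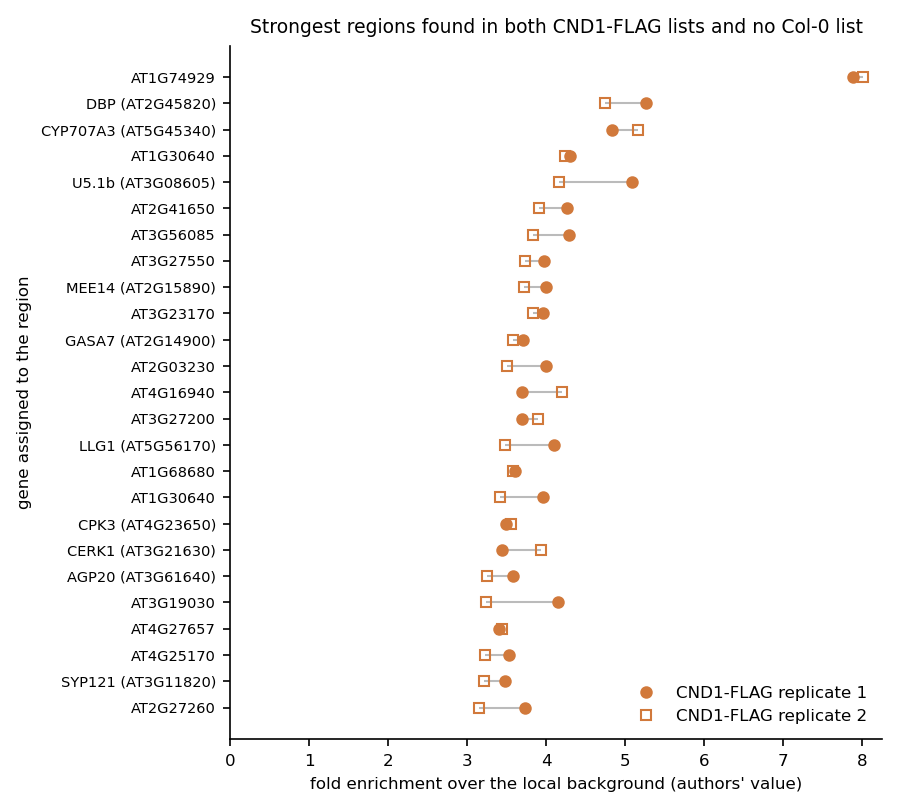
Fold enrichment of the 25 strongest tagged-specific regions in each CND1-FLAG list, named by the assigned gene. Each point is 1 library, and the region at AT1G74929 stands apart at 7.88 and 8.01, with the others at or below 5.26.

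Within each tagged list the next comparison sets the strength of tagged-specific regions against that of shared regions. The strongest peaks of the tagged lists were shared with Col-0. The region at TIF3F1 (AT2G39990; chromosome 2, 16700431 to 16702243), a translation initiation factor 3 subunit, had a fold enrichment of 9.85 and 10.6 in the tagged lists and of 5.43 and 5.19 in the Col-0 lists. ATJ11 (AT4G36040; chromosome 4, 17049275 to 17050441), a DnaJ protein of the chloroplast, had 9.47 and 9.90 against 5.21 and 5.30. ERD14 (AT1G76180; chromosome 1, 28585963 to 28587969), a dehydrin, had 9.004 and 9.28 against 4.69 and 4.65. AT5G11070 had 8.98 and 9.59 against 5.14 and 5.24, and AT2G23118 had 8.89 and 8.98 against 4.95 and 5.05. Fold values of different lists rest on different depths and inputs and are given side by side without a test.

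The median fold enrichment of tagged-specific regions was 1.93 against 2.03 for shared regions in CND1-FLAG replicate 1, a difference of −0.0977, and 1.90 against 1.97 in replicate 2, a difference of −0.0688. Both had a two-sided permutation p = 1e-05, the smallest value that 100000 permutations can give. The median −log10 q was 6.41 against 7.21 in replicate 1 (permutation p = 1e-05) and 5.46 against 5.83 in replicate 2 (permutation p = 0.00021). Regions within a list are not biological replicates. A region took the highest fold of each list, and shared nuclear regions held more summits than tagged-specific ones, 5440 against 4686 in replicate 1 and 5281 against 4547 in replicate 2. Part of the difference can therefore come from the merging. With a reciprocal overlap of 50%, where Col-0 peaks do not widen a region, the differences in median fold were −0.0828 and −0.0664.

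The genomic features of tagged-specific regions were compared with those of shared nuclear regions to ask where in genes they lie. Promoter sequence within 1 kb of a gene start held 71.4% of the tagged-specific regions, 2863 of 4011, and 68.1% of the shared regions, 2751 of 4038 (odds ratio 1.17, Fisher's exact test, two-sided, adjusted p = 0.00803 over 5 features). Regions whose strongest tagged peak overlaps the start of its assigned gene made up 15.8% of the tagged-specific and 12.6% of the shared regions (odds ratio 1.31, exact p = 3.72e-05, unadjusted). This share was not compared under the alternatives. Sequence 1 to 3 kb from a start held 19.0% and 20.4% (exact adjusted p = 0.205). Distal intergenic sequence held 7.58% and 9.01% (odds ratio 0.828, exact adjusted p = 0.0531), gene bodies beyond 3 kb held 1.12% and 1.46% (adjusted p = 0.249), and downstream sequence held 0.947% and 1.04% (adjusted p = 0.736). The promoter difference did not hold with −log10 q of at least 5 (odds ratio 0.994, exact adjusted p = 1), in the top 50% of each list (1.14, adjusted p = 0.307) or with any library left out (1.07 without Col-0 replicate 1, 1.03 without Col-0 replicate 2, 1.01 without CND1-FLAG replicate 1 and 0.972 without CND1-FLAG replicate 2). The distal intergenic odds ratio passed the test at 0.792 when an untagged peak within 500 bp counted as shared and at 0.463 with lists of equal length, and it turned to 1.22 (exact adjusted p = 0.00163) without CND1-FLAG replicate 2, to 1.14 (adjusted p = 0.272) without Col-0 replicate 1 and to 1.11 (adjusted p = 0.312) without CND1-FLAG replicate 1.

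The series asks about the genomes of the nucleus and the chloroplast, so the regions were also compared by chromosome. Organelle peaks appeared in the tagged lists and in neither Col-0 list: CND1-FLAG replicates 1 and 2 had 34 and 30 peaks on the plastid genome, covering 69.7 and 83.5 kb, and 77 and 94 peaks on the mitochondrial genome, covering 44.2 and 71.1 kb. The plastid held 24 tagged-specific regions and the mitochondrion 67. No shared region could lie on either, since neither Col-0 list had a peak there. Both counts were included in the tests by chromosome, but the lack of shared regions fixed their outcome. No conclusion is drawn from those p-values. Among the plastid regions were those at TRNH (ATCG00010, 23 to 3675), a histidine tRNA, ATPI (ATCG00150, 13921 to 26383), an ATP synthase subunit, and PSBD (ATCG00270, 32468 to 36029), the D2 protein of photosystem II, each with a fold enrichment of 1.17 and 1.303. All 24 plastid regions lay between 1.16 and 1.18 in replicate 1 and between 1.29 and 1.31 in replicate 2. The median plastid pile-up, worked out from fold and p-value, was at 100% and 99.8% of the most that 1 fragment per position and strand allows.

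The mitochondrial regions ran higher, from 1.13 to 2.16 in replicate 1 and from 1.19 to 2.32 in replicate 2, and 28 of the 67 exceeded 1.5 in both. The highest in replicate 1 was at ORF105A (ATMG01100, 281410 to 281812), with 2.16 and 2.28, and the highest in replicate 2 was at ORF294 (ATMG01200, 304040 to 304452), with 2.13 and 2.32. Another lay in exon 4 of 5 of NAD7 (ATMG00510, 135583 to 135945), a subunit of respiratory complex I, with 2.09 and 2.22. COX2 (ATMG00160, 40705 to 41987), a subunit of cytochrome c oxidase, had 1.15 and 1.25. On chromosome 2, a stretch from 3225849 to 3497767 held 42 tagged-specific and 2 shared regions, and 3969 nuclear tagged-specific regions lay outside it. This stretch, which holds an insertion of mitochondrial DNA, was chosen after its values were seen. Peaks from 3225849 to 3549843, a slightly longer window, numbered 52 and 58 in the tagged lists and 3 and 2 in the Col-0 lists. No plastid region remained with −log10 q of at least 5, in the top 50% of each list or with lists of equal length, and the mitochondrial share of 1.63% was 0.993% without CND1-FLAG replicate 2.

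**Figure D3:**
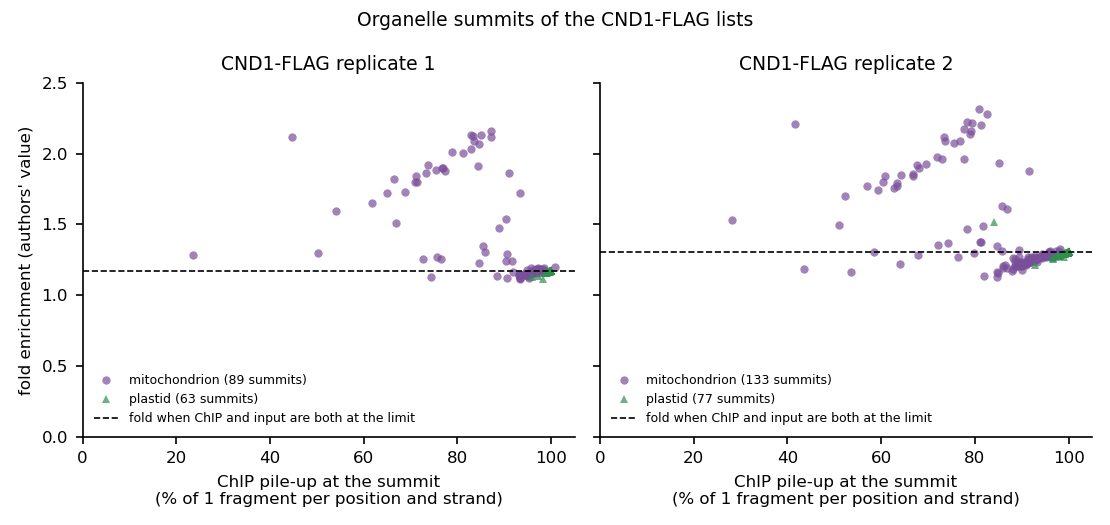
Fold enrichment of each plastid (triangles) and mitochondrial (circles) summit against its ChIP pile-up, in percent of the limit of 1 fragment per position and strand, for both CND1-FLAG lists, with a dashed line at the fold that follows when ChIP and input are both at the limit. Plastid summits gather at the limit and the line, with a median fold of 1.17 and 1.301 and 1 summit at 1.52 in replicate 2, while the highest mitochondrial summits lie below the limit with folds up to 2.16 and 2.32.

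Nuclear chromosomes held similar shares of both kinds of region. Chromosome 5 had 22.0% of the tagged-specific and 24.1% of the shared regions (Fisher's exact test, two-sided, p = 0.022, adjusted p = 0.0513 over 7 chromosomes), and chromosomes 1 to 4 had adjusted p-values of 0.665 or more. The 7 include both organelle genomes, whose small p-values were fixed by the lack of shared regions and lower the adjusted p of chromosome 5. An adjustment over the nuclear chromosomes alone was not run. With the organelle tests in the adjustment, the difference for chromosome 5 passed when an untagged peak within 500 bp counted as shared (21.9%, exact adjusted p = 0.041) and without Col-0 replicate 2 (22.0%, adjusted p = 0.0188). Whether it would pass without them was not tested. Pericentromeres, taken as round windows on each chromosome, held 12.4% of the tagged-specific regions, 497 of 4011, and 12.1% of the shared regions, 490 of 4038 (odds ratio 1.02, exact p = 0.734). The pericentromeric share of tagged-specific regions was higher than that of shared regions in 3 of the 4 sets with 1 library left out: 13.2% against 10.7% without Col-0 replicate 1 (exact p = 0.000803), 14.7% against 12.8% without CND1-FLAG replicate 1 (exact p = 0.00535) and 17.1% against 14.4% without CND1-FLAG replicate 2 (exact p = 3.8e-05). Without Col-0 replicate 2 it was 12.2% against 12.3% (exact p = 0.945).

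Gene lists fixed before the data were examined ask which nuclear functions carry tagged-specific regions. Genes of photosynthesis did so more often than other nuclear genes: 13 of 41, or 31.7%, against 9.71% (odds ratio 4.32, Fisher's exact test, two-sided, p = 8.86e-05, adjusted p = 0.00062 over 7 lists). The regions lay at PSBP1 (AT1G06680), of the oxygen-evolving complex, with a fold enrichment of 2.49 and 2.59, at LHCB4.1 (AT5G01530), a light-harvesting protein of photosystem II, with 2.25 and 2.14, at RBCS1B (AT5G38430), a small subunit of Rubisco, with 2.31 and 2.12, and at LHCA1 (AT3G54890), a light-harvesting protein of photosystem I, with 2.58 and 2.12. The 13 genes ran from 1.72 to 2.58 in replicate 1 and from 1.42 to 2.59 in replicate 2. Photosynthesis genes carried shared regions as well, at 18 of 41 genes, or 43.9% against 9.91% (odds ratio 7.11, exact adjusted p = 1.3e-07), among them LHCB1.3 (AT1G29930), with 4.53 and 3.95 in the tagged and 1.5 and 1.61 in the Col-0 lists, and FNR1 (AT5G66190), with 3.47 and 3.22 against 1.60 and 1.59. In all, 9 genes had tagged-specific regions alone, 14 shared regions alone, 4 both and 14 neither. Against genes with a peak in any list the tagged-specific share was 38.2% against 29.3% and did not pass the test (exact adjusted p = 1), and against genes matched for length it did (permutation adjusted p = 0.014).

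Highly transcribed housekeeping genes, a control list for the assay, carried tagged-specific regions at 7 of 30 genes, or 23.3% (odds ratio 2.83, exact p = 0.0226, adjusted p = 0.0791), and shared regions at 14 of 30, or 46.7% (odds ratio 7.95, exact adjusted p = 9.84e-07). Tagged-specific examples were ACT7 (AT5G09810), an actin, with 2.56 and 2.14, PIP1;2 (AT2G45960), an aquaporin, with 2.33 and 2.204, TUB2 (AT5G62690), a tubulin, with 2.19 and 1.998, and EF1A3 (AT1G07930), an elongation factor, with 1.99 and 2.08. In all, 5 genes of this list had tagged-specific regions alone and 2, ACT7 and EF1A3, also held a shared region. UBQ10 (AT4G05320), polyubiquitin, had a shared region, with 4.60 and 4.38 in the tagged and 4.34 and 4.19 in the Col-0 lists. The tagged-specific share of this list passed the test at 26.7% with a reciprocal overlap of 50% (exact adjusted p = 0.0245), at 20% with −log10 q of at least 5 (adjusted p = 0.0487), where a region whose Col-0 peaks fell below the threshold counts as tagged-specific, at 33.3% without Col-0 replicate 2 (adjusted p = 0.00412) and at 30.0% without CND1-FLAG replicate 1 (adjusted p = 0.0424). It did not pass with the other choices tried, among them lists of equal length (10%, exact adjusted p = 0.417), genes matched for length (permutation adjusted p = 0.507), protein-coding genes as background (exact adjusted p = 0.293) and genes with a peak in any list (29.2% against 29.3%, exact adjusted p = 1).

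DNA repair genes carried tagged-specific regions at 7 of 45 genes, or 15.6% (odds ratio 1.71, exact adjusted p = 0.353), and shared regions at 2 of 45, and the difference between these was not tested. Among them were TOP3A (AT5G63920; chromosome 5, 25574403 to 25574969), the topoisomerase that dissolves recombination intermediates, with a fold enrichment of 2.47 and 2.56, RAD5A (AT5G22750), of postreplication repair, with 1.996 and 1.67, SMR5 (AT1G07500), a cell cycle inhibitor induced by DNA damage, with 1.70 and 1.63, and ATR, LIG4 and ERCC1. Their share lay below that of other genes under stricter peak choices, at 4.44% against 6.77% with −log10 q of at least 5, 2.22% against 5.27% in the top 50% of each list and 2.22% against 4.04% with lists of equal length (exact adjusted p of 0.854 or more). Plastid transcription genes carried them at 4 of 22, or 18.18% (exact adjusted p = 0.353), and shared regions at none: TRXZ (AT3G06730) with 2.63 and 2.62, SIG4 (AT5G13730), a sigma factor, with 2.63 and 2.54, PTAC3 (AT3G04260) with 1.498 and 1.61, and PTAC10 (AT3G48500) with 1.36 and 1.92. DNA replication genes did so at 3 of 31, or 9.68% (exact adjusted p = 1): RPA1C (AT5G45400) with 2.38 and 1.83, the transcription factor E2FB (AT5G22220) with 2.15 and 2.04, and the DNA polymerase epsilon subunit POLE1 (AT1G08260) with 1.80 and 1.84. Cell cycle genes did so at 2 of 33, or 6.06% (exact adjusted p = 0.895): RBR1 (AT3G12280), the retinoblastoma homologue, with 1.58 and 1.40, and KRP4 (AT2G32710) with 1.39 and 1.57. Among 21 genes of organelle genome maintenance, GYRA (AT3G10690), a gyrase subunit, had a tagged-specific region with 2.55 and 2.25 (4.76%, exact adjusted p = 0.895). With −log10 q of at least 5 the share of this list was 14.3% against 6.77% of other genes (exact adjusted p = 0.294). That rise came from the 2 genes of this list with shared regions as listed, whose Col-0 peaks fell below the threshold. Of the 22 regions that the rule for named genes takes from the lists, 14 were tagged-specific with −log10 q of at least 5, 13 in the top 50% of each list and 12 with lists of equal length.

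**Figure D4:**
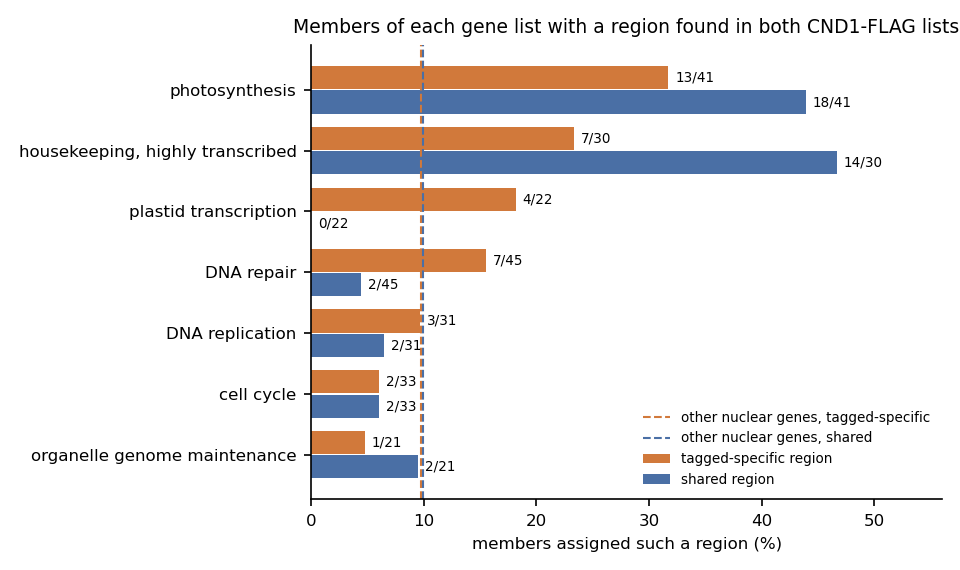
Percent of the genes of each list that carry a tagged-specific or a shared region, with dashed lines at the percent among other nuclear genes and the counts beside each bar. Photosynthesis reaches 31.7% for tagged-specific and 43.9% for shared regions, and the housekeeping control list reaches 23.3% and 46.7%.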

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

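Chosen only after the result was seen were the alternatives with summits in place of peaks, with protein-coding genes as background, with nuclear regions alone, and without the organelle genomes or the stretch of chromosome 2. Of 309 alternative values, 231 kept their direction and their side of the threshold or moved little, 12 became stronger, 8 weaker, 10 moved and 48 reversed, of which the distal intergenic odds ratio of 1.22 passed the test. List overlap stayed above random placement, but between genotypes it was 35.8% to 38.3% with lists of equal length. Peak numbers and peak strength kept direction throughout, with a tagged to Col-0 ratio between 1.78 and 2.197 with 1 library left out and of 1.98 with a replicate block, whose pairing rests on the replicate numbers alone. With −log10 q of at least 5 the tagged-specific count was 2719, the odds ratio of promoters within 1 kb reversed to 0.994, plastid regions fell to 0%, and the housekeeping share was 20% and passed the test. The top 50% of each list gave 2115 regions, a promoter odds ratio of 1.14 and a plastid share of 0%, and lists of equal length gave 1618 regions, a distal intergenic odds ratio of 0.463 and a plastid share of 0%. Counting an untagged peak within 500 bp as shared gave 0.823 for 1 to 3 kb, 0.792 for distal intergenic sequence and 21.9% for chromosome 5, each past the threshold, and a reciprocal overlap of 50% gave a housekeeping share of 26.7%. For chromosome 5 the adjustment included the organelle tests, whose outcome was fixed. With genes of any list as background the photosynthesis share was 38.2% and no longer passed. By covered length, the shares were 3.08% for the plastid, 2.24% for the mitochondrion and 14.0% for pericentromeres.

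Other values crossed to the opposite side of an even share without passing the test. With −log10 q of at least 5 these were the odds ratios of 1.09 for 1 to 3 kb and 1.034 for downstream sequence, and the shares of 20.7% for chromosome 3, 15.0% for chromosome 4, 6.15% for pericentromeres, 4.44% for DNA repair and 14.3% for organelle genome maintenance. In the top 50% of each list they were 1.059 for gene bodies, 20.3% and 15.2% for chromosomes 3 and 4, 2.22% for DNA repair and 9.52% for organelle maintenance, and with lists of equal length 20.1%, 15.5%, 2.22% and 4.76% for the same shares. A reciprocal overlap of 50% gave 15.2% for chromosome 2 and 20.7% for chromosome 3, and an untagged peak within 500 bp counted as shared gave 12.2% for pericentromeres and 9.68% for DNA replication. Without the stretch of chromosome 2 the shares were 14.6% for chromosome 2, 21.0% for chromosome 3 and 11.5% for pericentromeres. With promoters and gene bodies alone DNA replication had 9.68%, and with genes of any list as background it had 30%, housekeeping 29.2% and organelle maintenance 33.3%.

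With 1 library left out, the tagged-specific count ran from 4811 to 7753, the promoter odds ratio from 0.972 to 1.07, the distal intergenic odds ratio from 0.928 to 1.22 (reversed in all but the fit without Col-0 replicate 2), the chromosome 5 share from 22.0% to 22.7%, the pericentromere share from 12.2% to 17.1% and the housekeeping share from 26.7% to 33.3%. Ranges for other results with reversed values were 0.877 to 1.002 for 1 to 3 kb, 0.812 to 1.008 for downstream sequence, 15.4% to 15.8%, 20.6% to 21.1% and 14.8% to 15.1% for chromosomes 2, 3 and 4, 9.68% to 19.4% for DNA replication and 6.06% to 15.15% for the cell cycle. Fewer peaks, or fewer lists that must hold or lack a peak, change the counts by construction. For the other changes the cause was not tested. With 2 libraries per genotype the exact permutation test used here can give no p below 0.333, and the depth of each list limits which weak peaks were called. The motif alternatives were not run.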

Other observations

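Chosen only after the result was seen were the tests of plastid and mitochondrial pile-ups, of depth, of seed and pollen genes in shared regions, and of touch and wound genes without a shared region. All 4 lists used here were added after the strongest regions were seen and left out the genes seen there. Genes of the early response to touch and wounding held shared regions far more often than other protein-coding genes: 32 of 52, or 61.5%, against 12.4% (odds ratio 11.3, Fisher's exact test, two-sided, adjusted p = 4.28e-16 over 4 lists), and 30 of them had a region of all 4 lists. ZAT10 (AT1G27730), a zinc finger repressor, had a fold enrichment of 7.42 and 7.58 in the tagged and 5.63 and 4.74 in the Col-0 lists. JAZ1 (AT1G19180), a repressor of jasmonate signalling, had 7.37 and 7.32 against 4.98 and 5.09, WRKY40 (AT1G80840) had 5.91 and 5.32 against 3.17 and 3.27, and the cold response regulator CBF2 (AT4G25470) had 7.14 and 7.29 against 2.13 and 2.23. TCH4 (AT5G57560), a cell wall enzyme induced by touch, had 4.18 and 4.19 against 2.66 and 2.38.

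Ribosomal protein genes had tagged-specific regions at 6 of 18 genes, or 33.3% against 12.1% (exact adjusted p = 0.064), and shared regions at none (exact p = 0.155). Examples were RPL4A (AT3G09630), with 2.69 and 2.45, RPL8A (AT2G18020), with 2.66 and 2.33, and RPS5A (AT3G11940), with 2.07 and 2.47. Weaker and farther from the start were RPL24A (AT2G36620), with 1.70 and 1.45 at 1034 bp, and RPL9B (AT1G33140), whose distal intergenic region at −3644 bp had 1.92 and 1.735. Seed and pollen genes, such as OLEO3 (AT5G51210), an oleosin, with 2.79 and 3.10 against 1.38 and 1.52, and the seed storage gene SESA4 (AT4G27170), with 2.31 and 1.59 against 1.91 and 1.94, held shared regions at 11 of 19 genes, or 57.9% (exact adjusted p = 6.57e-06), and tagged-specific regions at 4 (exact p = 0.277). Heat shock genes had tagged-specific regions at 2 of 16, among them DREB2A (AT5G05410) with 3.00 and 3.15, and shared regions at 3 (exact p = 0.441).

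Organelle peaks were seen in the tagged lists alone, where plastid pile-ups had medians of 100% and 99.85% of the limit in CND1-FLAG replicates 1 and 2, for a limit of 1 fragment per position and strand, and there the scaling alone sets a fold of 1.17 and 1.303 in the tagged lists, where the input was scaled down, and of 0.724 and 0.740 in the Col-0 lists, where the ChIP was. A candidate explanation for the plastid peaks, and for mitochondrial summits that do not exceed the unscaled input (medians of 95.25% and 91.09% of the limit), is therefore saturation with scaling. Where ChIP and input are equal, pile-ups from 43.2% and 15.7% of the limit in CND1-FLAG replicates 1 and 2 already pass the threshold of the lists, so calling alone does not set those medians. Saturation leaves out part of the mitochondrial summits, since 36.0% in CND1-FLAG replicate 1 and 26.32% in replicate 2 exceeded the unscaled input by more than 3 SD of a Poisson count, with median folds of 1.88 and 1.93. In the stretch of chromosome 2 with mitochondrial sequence, 39 of 55 and 39 of 61 summits did so. Their median unscaled input was 308 and 313 fragments, against 305 and 308 for the mitochondrial summits that did so. The median background of tagged-specific nuclear summits, after scaling, was 43.6 and 39.4. Fragments of the mitochondrial genome placed on the insertion therefore cannot be told apart from fragments of the stretch itself. For these parts binding of tagged CND1 and other differences in organelle DNA between the plants remain open and untested.

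More peaks were called in tagged plants than in Col-0. Deeper tagged libraries are argued against, since the tagged ChIP libraries had 0.5126 times the fragments per kb of the Col-0 libraries. Chance dips in the 1 input that both tagged lists share stay open. The share of summits with the background at its lowest level was higher in tagged-specific than in shared regions by 1.293 and 1.301 percentage points, less than the 5 points set as a bound. However, just 7.47% and 6.91% of tagged-specific summits in CND1-FLAG replicates 1 and 2 lay at that level. A dip that left the background above it would not be counted, so the test cannot decide. The tag itself may account for the extra peaks as a hypothesis, and plant growth or chromatin preparation that differed between the genotypes remain open and untested.

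Touch and wound genes stood out in shared regions, which Col-0 plants without the tag gave too, so that tagged CND1 is not needed for those peaks. A touch or wound response that differed between the plants stays open. The list held tagged-specific regions at an odds ratio of 0.9464 (6 of 52 genes, exact p = 1), below the bound set beforehand as counting against such a response. But 32 of its genes had a shared region, where a difference in degree would not be counted. Among genes without one, a comparison chosen after the result was seen, the shares were 30% (6 of 20) against 11.97% (exact p = 0.0258, unadjusted). That excess is not particular to this list, since ribosomal protein genes had 33.3% against 11.97% (exact p = 0.0153), and among genes with a region 15.8% of touch and wound genes against 45.8% of others had tagged-specific regions alone, a share that the shared regions lower. A preference of the assay for transcribed genes may account for tagged-specific regions, as ribosomal protein genes held them at an odds ratio of 3.633 (exact p = 0.01601, adjusted p = 0.064). Counting only genes without a shared region gave 4.27 (exact adjusted p = 0.0323). It kept the same 6 ribosomal protein genes and lowered the share of others from 12.1% to 10.5%, so it adds no support. Among genes with a region, 6 of 6 ribosomal protein genes (100%) against 45.6% of others had tagged-specific regions alone (exact p = 0.00901, unadjusted). A preference that acted alike in both genotypes would not favour tagged-specific over shared regions. These 6 genes therefore go against a preference of that kind as their whole account. The housekeeping list had an exact adjusted p of 0.0791 against all nuclear genes and passed under 4 alternatives. Against protein-coding genes, the background used for ribosomal protein genes, its odds ratio was 2.21 (exact adjusted p = 0.293). Binding of tagged CND1 in the tagged-specific regions remains open and untested. For shared regions, against protein-coding genes, housekeeping genes (odds ratio 6.15) and photosynthesis genes (5.505) go with a preference of the assay for transcribed genes, while ribosomal protein genes (0 of 18) do not. Seed and pollen genes, taken as mostly silent in seedlings without expression data here, had an odds ratio of 9.658 against the same background (exact p = 3.28e-06). If they are silent, this argues against that preference as the whole account. Among them SESA1 to SESA4 lie side by side on chromosome 4 (13607307 to 13614134), and the test counts them as separate genes.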
